A study of Homo sapiens with 8 samples.

How the data were processed

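The series holds 8 libraries of human hepatic stellate cells, cultured in DMEM with serum per the labels' protocols, in 4 groups of 2: RNA-seq and ribosome profiling, each with control or LARP6 silencing RNA. Per the labels' protocols, RNA for RNA-seq was extracted with Trizol. For ribosome profiling, cycloheximide was applied, lysates were digested with RNase I, and ribosomes were pelleted by ultracentrifugation. The sources used here give neither the RNA selection (poly(A) or ribosomal RNA removal) nor the footprint size range. The submitters' processing notes name cutadapt, Bowtie, hg38 and GRCh38 without versions or order. How reads mapping to several places were counted, and the program that compared efficiencies, are not given in the sources used here. Reads from RNA fragments of footprint size that are not ribosome-bound would enter the efficiency of any transcript that gives them.

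The values are the authors' own comparison, with 12109 transcripts. Per the file headers, the deposited columns are log2 changes of translation efficiency from 2 methods and a final log2 change, the knockdown's log2 efficiency, and a p-value of each method, a final p-value and an adjusted p-value. The final p-value that the authors deposited equals the larger of the 2 methods' p-values in 12109 transcripts (relative tolerance 1e-09), and the adjusted p-value differs from Benjamini-Hochberg adjustment of it by at most 6.3e-15. The deposited log2 changes are relative to the typical transcript, with a median knockdown log2 efficiency of 0.0078. Control efficiencies were derived here as the knockdown log2 efficiency minus the second method's log2 change.

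The authors' deposited table has no values per library. The planned tests of RNA abundance, footprint abundance, their agreement, LARP6 level and the interaction model on counts were therefore not run, and the authors' comparison is described as theirs. No depth, standard error or interval can be given. The labels do not say that replicates were separate cultures, so the authors' p-values may measure only technical spread between samples.

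Transcript rows carry a gene name, or in 697 cases a transcript type, and the last 6 digits of a transcript identifier. These digits matched 11590 transcripts of GENCODE release 29 on GRCh38, from which coordinates, classes, GC content and lengths were taken; 519 transcripts did not match. Of 11005 named transcripts that matched, 10997 carried the same symbol. ATF4 and H3C10 did not match and have no coordinates here. The 13 names on more than 1 row were kept as separate transcripts.

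Before the data were examined, 29 gene lists, the threshold of an adjusted p of 0.05 and the rule for named genes were fixed. Each of the 25 lists with at least 5 measured members was tested with cameraPR of limma 3.58.1 in R 4.3.3, with a preset correlation of 0.01, on the final p-value turned into a z with the sign of the log2 change, and adjusted by Benjamini-Hochberg over the 25 lists. An estimated correlation and fry need values per library and were not run. A z grows with how well a transcript is measured, and a log2 change does not. Lists were therefore also tested on log2 changes in place of the z, without ranking. That test gives every transcript the same weight, however poorly it is measured. A rank test was run on ranks of the same z, so it still depends on how well a transcript is measured. On simulated data with 12109 transcripts and 20 draws, a shift of the collagen list by 1 SD was recovered in 95% of draws and a shift of the ribosomal protein list by 0.5 SD in 50%. Shifts of the proliferation list by 1 SD and of the p53 list by 0.5 SD were recovered in 100% and 25%, so smaller shifts of a list can be missed. Lists without a shift gave a p under 0.05 in 2.8% of cases. The simulated transcripts were drawn independently, so this rate does not cover lists whose members are correlated.

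Named genes were LARP6, COL1A1, COL1A2, COL3A1, ACTA2, FN1, TGFB1 and CCN2, then the 8 largest rises and 8 largest falls among protein-coding or named transcripts past the threshold. Then came up to 4 of the largest called members of each list that passed or had at least 2 called members. The rule also asked for an expression minimum and for agreement of every library, which could not be applied. Some genes that the rule takes are not reported here. VIM in the report and the genes opening the observations were chosen after their values were seen, as were the genes outside this rule named anywhere else. Single members of gene families with near-identical copies are uncertain.

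Alternatives planned before were other thresholds, the test on log2 changes and the rank test. Added after seeing the data were each method alone, protein-coding transcripts only, a preset correlation of 0.05, histones left out, and residuals of the z on GC content and lengths of 10560 protein-coding transcripts, which explained 2.46% of its variance. On simulated data with a GC trend, 12% of lists passed an unadjusted 0.05 before this correction and 2% after, over 20 draws of 10560 transcripts. No length trend was simulated, so the length part of the correction was not checked in this way. The GC trend was put into the z itself, so a trend that grows with how well a transcript is measured was not checked either. Features of called transcripts were compared by two-sided permutation tests with 100000 resamples over 10 tests. Python 3.11.15, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.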

Results

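Ribosome profiling and RNA-seq were carried out in human hepatic stellate cells, the liver cells that lay down scar matrix when activated. The cells are labelled as a cell line and received either a control silencing RNA or one against LARP6, a La-related RNA-binding protein described as binding collagen messages. Ribosome profiling sequences the RNA fragments that ribosomes protect from nuclease. The 8 libraries formed 4 groups of 2, with RNA-seq and ribosome profiling of control cells and of LARP6 knockdown cells. The authors' deposited table gives, for 12109 transcripts, the log2 change in translation efficiency, which is footprints relative to RNA, in the knockdown over the control. It carries no value per library, so no spread between replicates, standard error or sequencing depth stands beside the values, and the precision of each rests on the authors' p-value. The comparison asks which messages are translated more or less efficiently once LARP6 is depleted.

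After knockdown, the translation efficiency of the main fibrillar collagens and several other matrix proteins was lower. Footprints relative to RNA were also lower for replication-dependent histones, but the RNA selection is not known, so this may not be a change in translation. Translation efficiency was higher for IL11 and several members of a list of matrix proteases and their inhibitors, while other members of that list fell. In the authors' deposited table, 266 of the 12109 transcripts (2.20%) passed an adjusted p of 0.05, of which 130 were higher and 136 lower after knockdown. An unadjusted p under 0.05 was reached by 1246 transcripts (10.3%) of the authors' deposited table. The changes were mostly moderate, with a median absolute log2 change of 0.88 among the called transcripts of the authors' deposited table, 110 of which changed at least 2-fold. The authors' deposited table lists 2 estimates per transcript and a final one. The 2 estimates are nearly the same (Pearson r of 0.999 across transcripts), so their shared sign in all 266 called transcripts is no independent check. Of the called transcripts in the authors' deposited table, 245 are annotated as protein-coding. The efficiencies are scaled to the typical transcript, with a median log2 change of 0.015 in the authors' deposited table, so a change shared by all messages would not show.

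LARP6 itself (chromosome 15, 70829130 to 70854159, GRCh38) had a log2 change in efficiency of 0.07 with an adjusted p of 0.98 in the authors' deposited table. This is a ratio of footprints to RNA and does not check the knockdown, since a loss of LARP6 RNA lowers both; LARP6 abundance was not analysed here. None of the 6 measured La-related proteins was called in the authors' deposited table (list adjusted p = 0.778, cameraPR). Among 10 proteins described as partners of LARP6, the intermediate filament protein VIM rose, by 0.40 on the log2 scale, in the authors' deposited table, and 7 lay below 0 (list adjusted p = 0.955, cameraPR; median −0.25, mean −0.14, test upward).

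**Figure D1:**
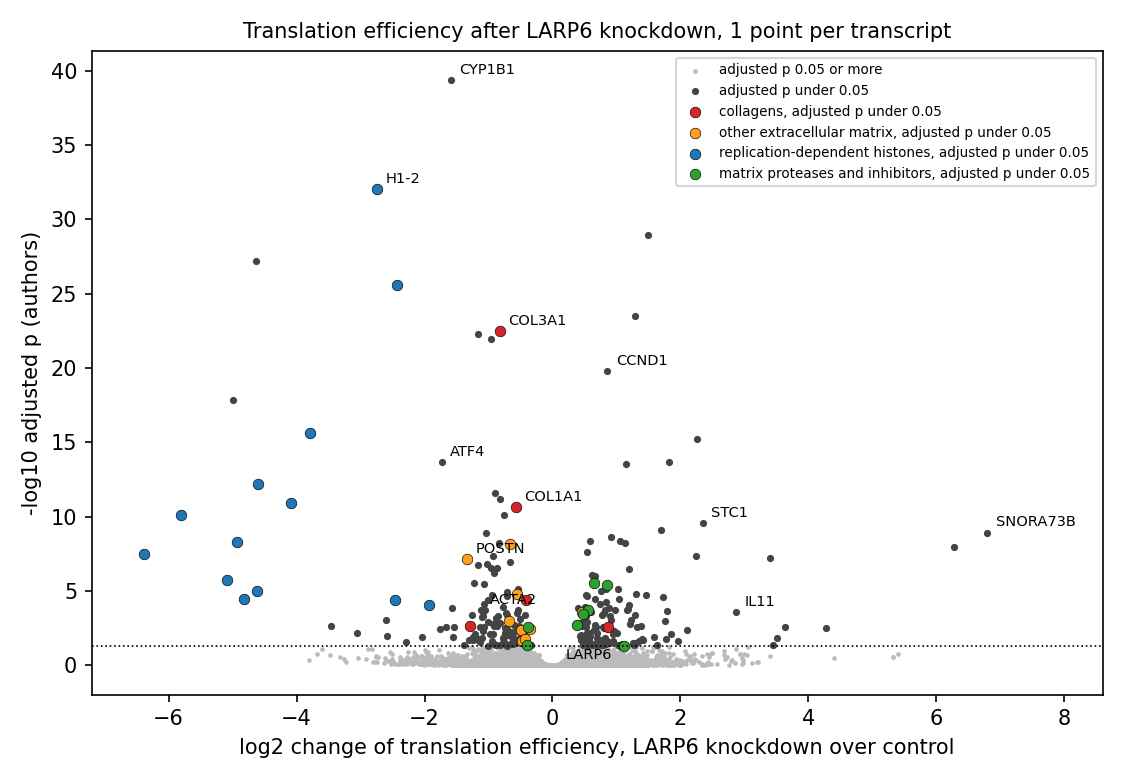
Log2 change in translation efficiency, LARP6 knockdown over control (x axis), against the −log10 adjusted p of the authors' deposited table (y axis), with 1 point per transcript and the dotted line at an adjusted p of 0.05. Coloured points are called members of 4 gene lists; the histones reach −6.39 and COL3A1 lies at −0.82.

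Among collagens more members fell than rose. Of 21 measured collagens, 4 fell and 1 rose in the authors' deposited table, and the same numbers passed when adjusted over the list alone. COL3A1, the chain of type III collagen (chromosome 2, 188974320 to 189012746), was 1.76-fold lower (adjusted p = 3.2e-23) in the authors' deposited table. Both type I collagen chains fell as well in the authors' deposited table, COL1A1 (chromosome 17, 50183289 to 50201632) by 0.57 on the log2 scale (adjusted p = 2.3e-11) and COL1A2 (chromosome 7, 94394561 to 94431232) by 0.42 (adjusted p = 4.0e-05). The fibril-associated COL12A1 fell by 1.28 (adjusted p = 0.0022) in the authors' deposited table, and COL5A3 rose by 0.86 (adjusted p = 0.0026). As a list the collagens lay below the other transcripts (median −0.08, adjusted p = 0.000165, cameraPR with a preset correlation of 0.01). That call was lost when cameraPR was run on log2 changes (adjusted p = 0.529) or on ranks of the z (adjusted p = 0.219). Of the 21 members, 9 lay above 0.

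Other extracellular matrix proteins were mostly lower. In the authors' deposited table, 8 of 44 members fell and 1 rose, or 13 and 2 when adjusted over the list alone, and 33 of the 44 lay below 0. POSTN, the matricellular protein periostin, was 2.52-fold lower (adjusted p = 7.4e-08) in the authors' deposited table. The small proteoglycans LUM and DCN fell by 0.68 and 0.66 on the log2 scale in the authors' deposited table, and fibronectin, FN1 (chromosome 2, 215360454 to 215436172), fell by 0.56 (adjusted p = 1.6e-05). The list test gave an adjusted p of 2.9e-08 downward (cameraPR, median −0.22). The list also passed in the rank test of the z (adjusted p = 0.0001825) but not on log2 changes (adjusted p = 0.349). Enzymes and chaperones of collagen folding and processing did not move as a list (adjusted p = 0.468, cameraPR; median 0.02, mean −0.02, test downward). Within it, 3 of 31 members fell in the authors' deposited table, namely LOXL3 by 0.81, the collagen chaperone SERPINH1 by 0.45 and the cross-linking enzyme LOX by 0.43 on the log2 scale; 1 member was higher and 3 lower when adjusted over the list alone.

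The translation efficiency of contractile and cytoskeletal genes went both ways. ACTA2, smooth muscle actin and the usual marker of activated stellate cells (chromosome 10, 88935074 to 88952773), was 2.16-fold lower (adjusted p = 0.000185) in the authors' deposited table. The actin-binding protein CALD1 fell by 0.56 on the log2 scale in the authors' deposited table, whereas the LIM protein CSRP1 and beta-actin ACTB rose by 0.66 and 0.67. ACTA2 and ACTB belong to a family of near-identical genes, and how shared reads were assigned is not given in the sources used here. In all, 4 of 28 contractile and cytoskeletal genes rose and 3 fell in the authors' deposited table, 5 and 5 when adjusted over the list alone, and the list did not pass (adjusted p = 0.778, cameraPR; median 0.04, mean −0.04, test upward). None of 13 markers of quiescent stellate cells was called in the authors' deposited table (list adjusted p = 0.822, cameraPR).

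TGF-beta signalling genes, which drive stellate cell activation, did not move together (37 members, adjusted p = 0.457, cameraPR; median 0.04, mean −0.02, test upward). TGFB1 had a log2 change of −0.01 (adjusted p = 0.99) in the authors' deposited table. CCN2, connective tissue growth factor, fell by 0.35 on the log2 scale (adjusted p = 0.0035) in the authors' deposited table. In the list 2 genes rose and 2 fell in the authors' deposited table, and likewise when adjusted over the list alone: the activin subunit INHBA rose by 0.62 and the latent TGF-beta carrier LRRC32 by 1.05, and the transcriptional regulators ID1 and ID2 fell by 0.71 and 1.25 on the log2 scale.

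Among matrix proteases and their inhibitors more members rose than fell. In the authors' deposited table, 6 of 29 members rose and 2 fell, 6 and 3 when adjusted over the list alone. Among those that rose in the authors' deposited table were urokinase PLAU by 1.12 (adjusted p = 0.049), its receptor PLAUR by 0.86, the protease inhibitor SERPINE2 by 0.64 and cathepsin L, CTSL, by 0.56 on the log2 scale. Cathepsin K, CTSK, was among those that fell in the authors' deposited table, by 0.40 (adjusted p = 0.040). The list passed (adjusted p = 0.0146, cameraPR, median 0.10). It did not pass on log2 changes (adjusted p = 0.79), in the rank test (adjusted p = 0.219) or with a preset correlation of 0.05 (adjusted p = 0.149). Of 28 integrins and growth factor receptors, 2 rose and 2 fell in the authors' deposited table, or 5 and 3 when adjusted over the list alone (list adjusted p = 0.312, cameraPR). The integrin subunits ITGB3 and ITGA2 rose by 0.98 and 0.68 on the log2 scale in the authors' deposited table, while the collagen receptor DDR2 and the platelet-derived growth factor receptor PDGFRB fell by 0.93 and 0.57.

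Replication-dependent histones, made in S phase from messages without a poly(A) tail, showed the largest falls among called transcripts. Of 21 measured members, 13 fell and 0 rose in the authors' deposited table, 14 and 0 when adjusted over the list alone, with a list median of −2.74 (adjusted p = 6.6e-53, cameraPR). The 89 names of this list include older and current symbols of the same genes, so they are not 89 genes. The largest fall among called transcripts of the authors' deposited table was in H4C4 (chromosome 6, 26188765 to 26189076), with a log2 change of −6.39 (adjusted p = 3.2e-08), followed by H2BC8 at −5.81 and H2AC8 at −5.09. The log2 changes of H2AC7 (−4.99), H3C10 (−4.93), H2BC4 (−4.82), the overlapping transcript AL031777.3 (−4.64) and H2AC11 (−4.62) complete the 8 largest falls among called transcripts of the authors' deposited table. AL031777.3 overlaps H2AC7 and H3C4 (−4.61 in the authors' deposited table), and the histone genes are near-identical copies, so single members are uncertain. The derived control log2 efficiency of the list had a high median of 4.13. How RNA was selected is not given in the sources used here, so these falls may not be changes in translation. The proliferation list did not move (30 members, adjusted p = 0.457, cameraPR), with 1 member higher in the authors' deposited table, also when adjusted over the list alone.

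The 8 largest rises among called transcripts were led by small nuclear and nucleolar RNAs, which are not translated. In the authors' deposited table SNORA73B (chromosome 1, 28508559 to 28508762) and SNORA73A rose by 6.80 and 6.28 on the log2 scale, the U5 spliceosomal RNAs RNU5B-1 and RNU5A-1 by 4.27 and 3.64, and SNORD10 by 3.51. Footprints per RNA of such a transcript is not a translation rate. The host gene SNHG25, which overlaps the small nucleolar RNA SNORA50C (log2 change 5.32, adjusted p = 0.29), rose by 3.44 and AC138811.2, which overlaps ARL6IP1 and RPS15A, by 3.41 in the authors' deposited table. The one of the 8 with a known secreted product was IL11, a profibrotic interleukin (chromosome 19, 55364389 to 55370373), 7.33-fold higher (adjusted p = 0.000258) in the authors' deposited table. Among 22 inflammatory cytokines and related genes 3 rose and 1 fell in the authors' deposited table, 4 and 6 when adjusted over the list alone. Besides IL11, the cytokine LIF rose by 1.38 and the prostaglandin E synthase PTGES by 0.83, and TNFAIP6 fell by 1.13 on the log2 scale in the authors' deposited table. That list did not pass (adjusted p = 0.822, cameraPR), nor did the 39 interferon response genes (adjusted p = 0.468, cameraPR; 0 called in the authors' deposited table).

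A few genes of the translation machinery rose. Of 39 measured cytosolic ribosomal proteins, out of 80 listed, 30 lay above 0 and 2 rose in the authors' deposited table, also when adjusted over the list alone, among them RPL37A by 1.31 on the log2 scale. The list median was 0.45 (adjusted p = 0.00178, cameraPR; 0.0765 with a preset correlation of 0.05). Ribosomal protein genes have many processed pseudogenes, so these members are uncertain. Elongation factor EEF2 and the initiation factor subunit EIF3D rose by 0.41 and 0.56 in the authors' deposited table, 2 of 40 factors, also when adjusted over the list alone (list adjusted p = 0.312, cameraPR). Mitochondrial ribosomal proteins (75 members, adjusted p = 0.822), oxidative phosphorylation (70 members, adjusted p = 0.0885) and protein targeting (48 members, adjusted p = 0.662) did not pass by cameraPR.

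Stress response genes included falls and rises. ATF4, the transcription factor of the integrated stress response, was 3.32-fold lower (adjusted p = 2.0e-14) in the authors' deposited table, and its target DDIT3 fell by 1.22 on the log2 scale. The amino acid transporter subunit SLC3A2 and the transcription factor CEBPB rose by 0.50 and 0.57 in the authors' deposited table. With 2 of 29 members higher and 2 lower in the authors' deposited table, 2 and 4 when adjusted over the list alone, the list test gave an adjusted p of 0.0368 downward (cameraPR, median −0.20). It did not pass under 6 of the 8 other settings. The adjusted p was 0.196 among protein-coding transcripts alone, 0.2 in the rank test and 0.369 on log2 changes (cameraPR). ATF4 itself is missing from the protein-coding setting, because its identifier matched no annotated transcript. Hypoxia and glycolysis genes had a median of 0.33 (33 members, adjusted p = 0.0211, cameraPR). The adjusted p was 0.19 with a preset correlation of 0.05 and 0.467 on log2 changes. PKM, pyruvate kinase, was the member that rose, by 0.45 on the log2 scale in the authors' deposited table. Endoplasmic reticulum chaperones (31 members, adjusted p = 0.778; median 0.006, mean −0.04, test downward), p53 targets (25 members, adjusted p = 0.468) and cholesterol synthesis (24 members, adjusted p = 0.915; median −0.02, mean 0.002, test upward) did not pass by cameraPR; 1 chaperone was higher and 1 p53 target lower in the authors' deposited table. The counts were the same when adjusted over the list alone for the hypoxia, chaperone, p53, oxidative phosphorylation (1 higher) and LARP6 partner lists, and stayed at 0 for the La-related, quiescent, interferon, mitochondrial ribosomal, targeting and cholesterol lists.

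**Figure D2:**
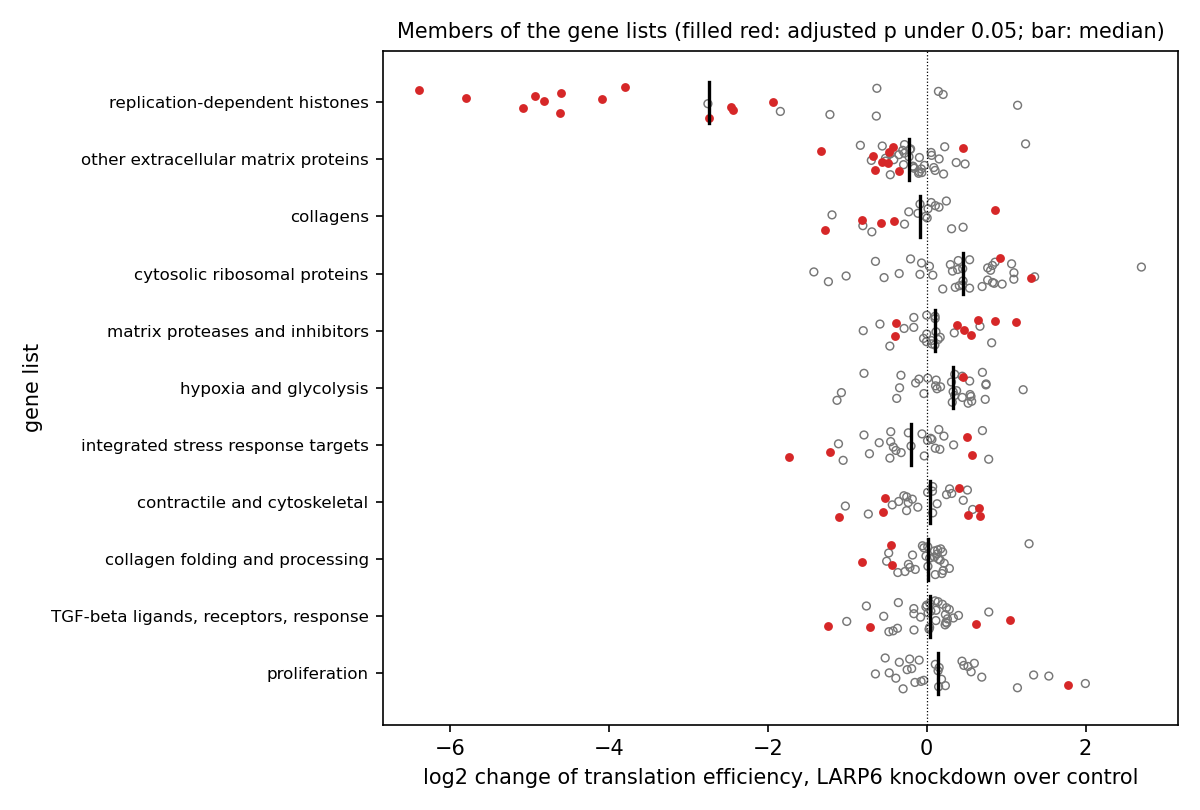
Log2 change in translation efficiency, LARP6 knockdown over control (x axis), of each measured member of 11 gene lists (y axis), from the authors' deposited table. Filled red points passed an adjusted p of 0.05, open points did not, and bars are list medians, which run from −2.74 for the histones to 0.45 for cytosolic ribosomal proteins.

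Markers of other liver cells were sparse. In the authors' deposited table, 2 of 24 listed hepatocyte markers, 4 of 19 endothelial and 2 of 22 leukocyte and Kupffer cell markers were measured, and 0 were called; these lists were too small to test. Of 7 biliary and epithelial markers 0 were called in the authors' deposited table, although 2 rose when adjusted over the list alone (list adjusted p = 0.312, cameraPR). On log2 changes the list adjusted p was 0.0461 (cameraPR). Among the 4 measured mitochondrially encoded messages of the authors' deposited table, also too few to test, MT-CO3 fell by 2.28 and MT-ND5 rose by 1.14 on the log2 scale. Footprints were sparse relative to RNA, with a median knockdown log2 efficiency of −4.82 for the 4 messages and −7.09 for MT-CO3.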

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

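Each method alone, protein-coding transcripts only, the preset correlation of 0.05, histones left out and the GC and length residuals were chosen after the data were seen. No paired analysis was possible because the authors' deposited table gives no value per library. For the same reason the planned count models, normalizations, filters, pseudocounts, leave-one-out runs, estimated correlation and fry were not run. Depth is unknown, so it is open which transcripts were too shallow to be called. For the 266 calls in the authors' deposited table, an adjusted p under 0.01 left 86 higher, a minimum of 2-fold left 110 (52 higher, 58 lower), and method 1 alone gave 457 (263 higher). The other thresholds, method 2 and protein-coding transcripts kept these counts within 1.5-fold. Since the final p is the larger of both methods' p-values, a called gene cannot lose its call under either method; of the named genes not called, 1 passed, under method 2. Of 25 list tests, 7 passed, against 3 on log2 changes, 4 in the rank test and 3 with a preset correlation of 0.05. Histones passed under every setting that kept them. Beyond the losses given in the report, integrated stress response reached 0.0642 with method 1, 0.153 on residuals and 0.217 with a preset correlation of 0.05, and hypoxia 0.0764 on residuals. The transcripts used for residuals leave out ATF4. Without the correction they already gave the stress response list an adjusted p of 0.197 (cameraPR). Biliary and epithelial markers gained a call on log2 changes (adjusted p = 0.0461, cameraPR). So did type I interferon with method 2 (adjusted p = 4.5e-07) and oxidative phosphorylation on residuals (0.0424). No called result reversed under any of these settings, and the cause of the differences was not tested.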

Other observations

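All genes, groups and tests of this part were chosen after the data were seen, apart from the collagen, matrix, protease and histone lists; for the GC and length tests the deciding bounds were written before their outcome was known. The smallest adjusted p of the authors' deposited table belonged to CYP1B1, a cytochrome P450 of steroid and retinoid metabolism (chromosome 2, 38067507 to 38076181), with a log2 change of −1.58 (adjusted p = 4.3e-40). Among enzymes of small lipid mediators, the authors' deposited table gives log2 changes of −1.16 for the prostacyclin synthase PTGIS and −1.23 for the cortisol-activating HSD11B1, but 0.83 for PTGES, 0.44 for the cyclooxygenase PTGS1, 0.83 for the lipase MGLL and 0.90 for the sphingosine kinase SPHK1. Of single secreted factors, BMP2 (1.79), BMP6 (0.84), GDF6 (0.94), the BMP antagonist GREM1 (0.52) and the Wnt antagonist SFRP1 (1.16) were higher on the log2 scale in the authors' deposited table, while the activin antagonist FST (−0.90) and SFRP4 (−1.07) were lower. The thrombin and protease receptors F2R (0.74) and F2RL1 (1.46) and thrombomodulin, THBD (0.78), were higher in the authors' deposited table. So were ANGPTL4 (2.27) and STC1 (2.35), both secreted, in the authors' deposited table.

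Called protein-coding transcripts differed in GC content. In 5′ untranslated regions the median was 69.6% for those higher, 63.7% for those lower and 67.7% for those not called (higher against lower, two-sided permutation p = 1e-05, the smallest 100000 resamples can give; adjusted p = 0.0001 over 10 tests). Without histones the median of the lower group was 64.4% (adjusted p = 0.00115). The GC content of coding sequences had medians of 56.9% for those higher and 53.9% for those lower (adjusted p = 0.062), and 56.9% and 53.6% without histones (adjusted p = 0.0188). Lengths of the coding and untranslated regions did not pass in either set. The interferon genes RSAD2 and IFIT2 had log2 changes of 2.45 and 1.77 in the authors' deposited table, with p-values of 2.2e-38 and 9.7e-36 by the second method but final p-values of 0.0141 and 0.0401.

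In the authors' deposited table, 4 of 21 collagens and 8 of 44 other matrix proteins fell. On log2 changes neither list passed (adjusted p = 0.529 and 0.349, cameraPR). In the rank test the collagens did not pass either (0.219), while the matrix list did (0.0001825). On residuals the matrix list kept an adjusted p of 1.2e-07 and the collagens 0.000337 (cameraPR). This argues against an average trend of the z with GC content or transcript length as the whole cause. A trend that grows with how well a transcript is measured would not be removed by this correction, so it stays open. A fall of secreted proteins in general stays open. Of 29 proteases and inhibitors 6 rose and 2 fell, but that list also holds proteins that are not secreted, such as the receptor PLAUR. The list's own call also depends on the setting of the test. A hypothesis from the described binding of LARP6 to a 5′ stem-loop of COL1A1, COL1A2 and COL3A1 is that these fall more than other collagens; the exact one-sided permutation p was 0.000752 on the z, the smallest the 1330 choices can give, but 0.0932 on the log2 change (means −0.60 and −0.14). The z grows with abundance and was the first of these measures tried, so the hypothesis stays open, as does whether footprints or RNA moved.

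Replication-dependent histones had 3 of 21 measured members above 0. The 89 listed names give genes under both older and current symbols, but not every listed gene was measured. Reads moving to copies outside the measured ones therefore stay open. Replication-independent histones had a median log2 change of 0.289, against a change of all histone genes. An RNA library that under-represents messages without a poly(A) tail is in line with the high derived control efficiency (median log2 4.13, against 1.03 in the knockdown) but does not by itself account for a change between conditions. A knockdown library prepared or composed differently and a change in S-phase cells both stay open, since RNA and footprints were not analysed separately here. Small nuclear and nucleolar RNAs, which also lack the tail, went the other way: 31 of 37 lay above 0 with a median of 2.58, and 5 were called higher and 0 lower, which may reflect fragments in the footprint libraries that are not ribosome-bound.

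Several targets of the MAPK pathway had a higher translation efficiency. This is footprints relative to RNA and not the level of the message, so the values do not measure the pathway's activity. Of the 10 measured genes of a published MAPK activity score, 4 rose and 6 were not called in the authors' deposited table, with 4 higher and 1 lower when adjusted over the list alone. DUSP6 (2.25), SPRY2 (1.01), PHLDA1 (0.92) and CCND1 (0.86, adjusted p = 1.6e-20) rose on the log2 scale in the authors' deposited table, against values of −2.10 for EPHA4, −0.38 for EPHA2, 0.05 for ETV5 and 0.45 for SPRY4. The list was chosen because members had been seen to rise, so its test is no independent evidence, and its adjusted p was 0.0502 by ranks. On residuals the adjusted p was 5.8e-10 (cameraPR), against 1.4e-09 on the same transcripts uncorrected. Correction for GC content and length thus did not weaken the rise, but both values come from the list chosen for that rise. A rise of short-lived messages in general stays open. The 34 others had a median of −0.17, of which 8 fell and 1 rose in the authors' deposited table. Their list gave an adjusted p of 9.5e-05 downward (cameraPR over 3 lists), but 0.0796 by ranks. That list also left out 8 such genes called higher in the authors' deposited table, among them JUN (1.02) and IER2 (1.30). Altered growth factor signalling is a candidate explanation that was not tested, and a ratio of footprints to RNA cannot test it alone.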
